A study of Mus musculus with 2 samples.

How the data were processed

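Short RNAs from mouse heart were sequenced in 2 libraries, and each library came with 1 table of raw read counts per miRNA gene. The deposited tables have no header. Per the text deposited beside them, the authors used the mm10 assembly and annotation M21. The aligner, the counter and their settings are not given in the sources used here. The deposited counts are whole numbers that the authors had not normalized, in 3 columns for both strands together, the sense strand and the antisense strand. Which strand a column holds was read from the values, since 1 stranded column holds nearly all gene reads. The labels say nothing of molecular identifiers. The first 4 rows of each table name no gene and give the reads that were unmapped, mapped to several places, fell in no miRNA gene or were ambiguous. They were kept out of totals and tests.

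All 2202 gene identifiers matched miRNA genes of the GENCODE annotation M21, from which symbols, positions and host genes were taken. A hairpin was placed in an exon where it overlapped any exon of any annotated transcript of its host gene. It can therefore be intronic in other transcripts of that gene. Of all reads, 14.9% in library 1 and 13.8% in library 2 were unmapped, 41.5% and 42.9% mapped to several places, 7.09% and 5.29% mapped once outside miRNA genes, and 36.5% and 38.1% were assigned to a miRNA gene on the sense strand. Reads mapping to several places were not assigned to genes in these tables, so a miRNA made from near-identical loci can be undercounted at each. With both strands counted together, 7.90% and 9.21% of reads were ambiguous, because 64 genes have a miRNA gene on the opposite strand. Those genes held 21.7% and 24.2% of sense-strand reads, among them Mir378a, Mir126a and Mir451a, so the sense-strand column was used throughout.

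The labels place both libraries in 1 group, the heart of young males, as replicates 1 and 2. The age and source fields give 36 days, and a free-text field gives the same number with months as the unit; days were used. Both libraries are numbered as different males but carry the same donor record, so the labels leave open whether that record stands for a strain or an animal, and SDs measure the spread between these samples. No replicate-based test between conditions was possible, and the p-values between libraries rest on counting error alone. The libraries were not copies of each other, with a chi-square of 92268 on 343 degrees of freedom over tested genes.

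CPM were computed over assigned sense-strand reads. A gene was called detected at 10 CPM. Shares have exact Clopper-Pearson 95% intervals, and the floor is 3 counts, 1.5 CPM in library 1 and 1.61 CPM in library 2, which holds for loci whose reads map to a single place. The ratio of Mir208a to Mir208b has an exact binomial interval. Genes with 10 or more counts summed over both libraries entered the comparison of libraries, an exact two-sided conditional binomial test against the ratio of assigned totals, with Benjamini-Hochberg adjustment at 0.05 and a CPM ratio of 2-fold or more. Log2 ratios had 0.5 added to each count. The biological coefficient of variation is the square root of edgeR's common dispersion with an intercept-only design and TMM factors, with an interval from 100 draws of genes, and the interval of Spearman's rho came from 1000 draws of genes. The Pearson correlation used log2(CPM + 1).

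The genes named are the 20 with the highest mean CPM, members of 23 fixed lists at a mean of 100 CPM or more (or the highest member where none reached it), and the 5 largest ratios in each direction among genes past the test at 100 CPM or more. From the lists, the leading members are given in the text and the rest as list sums. Genes outside this rule are said to be so where they appear, and the members of the cardiac muscle list are all given. The lists are cardiac muscle, skeletal muscle cluster, endothelial, smooth muscle, fibroblast and mesenchymal, erythroid, leukocyte, neuronal, hepatic and intestinal, epithelial, pancreatic, pluripotent stem cell, let-7, mir-30, mir-29, mir-26, mir-23/27/24, mir-15/16, mir-17-92 with paralogs, metabolic and stress, Dlk1-Dio3, Sfmbt2, and entries resembling ribosomal RNA. Groups, lists, the tests of the report, the naming rule and the alternatives were fixed before the data were examined, while most tests of the closing section, the 22 nt criterion among them, were not. Loci were called near-identical when their annotated hairpins share a stretch of 22 nt, about the length of a mature miRNA, with another hairpin. No genome sequence was used, so copies outside annotated miRNA genes were not searched.

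The alternatives were counts of both strands together, other detection thresholds, all reads as the denominator, other pseudocounts and count filters, TMM and DESeq2 scaling, other fold thresholds, loci with numbered copies left out, the most abundant gene left out, and each replicate left out. The count test was tested on simulated data for the comparison of library 2 with library 1 over 344 genes. The simulated counts held counting error alone and no spread between samples. The test called 89% of genes changed 3-fold, 96% of genes changed 8-fold and 0.694% of 144 unchanged genes. These rates do not carry over to libraries that also vary beyond counting. Simulated coefficients of variation of 0.2, 0.4 and 0.8 were recovered as 0.195, 0.361 and 0.787. The pair test of the closing section was simulated for pairs of the same family, permuted over all genes. With no effect it gave a p under 0.05 in 12 of 200 draws of independent normal values. Permutation within abundance quartiles and pairs of cluster neighbours were not simulated with no effect. Signal tracks and alignments of these libraries were not used here.

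Software was Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.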

Results

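MicroRNA-seq, the sequencing of short RNAs, was applied to total RNA from the hearts of male B6CASTF1/J mice, the F1 hybrid of the B6 and CAST inbred strains, aged 36 days by the age label, against which a free-text label gives months as the unit. The 2 libraries form 1 group, and the labels number them as biological replicates from differently numbered males, although both carry the same donor record, so n = 2 counts samples. No treatment, second tissue or second age was labelled, so the design implies a description of the heart miRNA profile and a comparison of the 2 replicate libraries, and no contrast between conditions. Library 1 held 5479149 reads and library 2 held 4893073. Of these, 1999362 and 1862526 were assigned to a miRNA gene on its own strand, a mean of 37.3% ± 1.11 (SD, n = 2) of all reads. All levels below are counts per 1000000 (CPM) of these assigned sense-strand reads, given as mean ± SD over n = 2 libraries unless stated otherwise, and positions are those of the mm10 assembly. Each gene level sums all reads of a hairpin, so the mature arms are not separated.

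Among reads placed on a single miRNA gene, Mir378a and the let-7 family had the highest levels. A further 42.2% ± 0.987 of all reads mapped to several places and were assigned to no gene, so miRNAs made from near-identical loci are missing from this ranking to an unknown extent. Mir378a was the most abundant miRNA gene at 143048 ± 10180 CPM, or 14.3% ± 1.02 of assigned reads. It lies on the minus strand of chromosome 18 from 61397835 to 61397900, in an intron of Ppargc1b, which encodes a coactivator of mitochondrial and metabolic genes. Mirlet7i followed at 92476 ± 7048 CPM (chromosome 10, 122985640 to 122985724, outside other annotated genes), and Mirlet7g at 79484 ± 10236 CPM in an intron of Wdr82 (chromosome 9, 106178840 to 106178927). Mir23b reached 57952 ± 118 CPM (chromosome 13, 63300484 to 63300557). Mir126a, which is known from endothelial cells, reached 56371 ± 10533 CPM (chromosome 2, 26591357 to 26591429). It lies within Egfl7 and overlaps an exon of at least 1 annotated transcript, so it can be intronic in others.

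The next genes in order were Mirlet7b at 51621 ± 1021 CPM, Mirlet7d at 50072 ± 3731, Mir139 at 44696 ± 2411 in an intron of Pde2a, Mir22 at 42480 ± 25466 and Mir23a at 42206 ± 13034. Together the 10 most abundant genes took 66.0% ± 1.09 of assigned reads. Mir143 (37774 ± 705 CPM), Mir99a (31684 ± 2450), Mir26b (26041 ± 6194, in an intron of Ctdsp1), Mir149 (19969 ± 3600, in an intron of Gpc1) and Mir30d (13606 ± 5576) came next. The 20 highest also held Mir191 (11885 ± 121 CPM), Mir30a (10085 ± 180), Mir125a (10073 ± 626), Mir652 (8140 ± 1779) and Mirlet7f-2 (7132 ± 150), and took 83.7% ± 0.613 of assigned reads. The SD of Mir22, Mir23a and Mir30d was a large part of the mean, so their order against neighbours was within the spread of the libraries. Of these 20 genes, 16 lie inside an annotated host gene on the same strand.

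**Figure D1:**
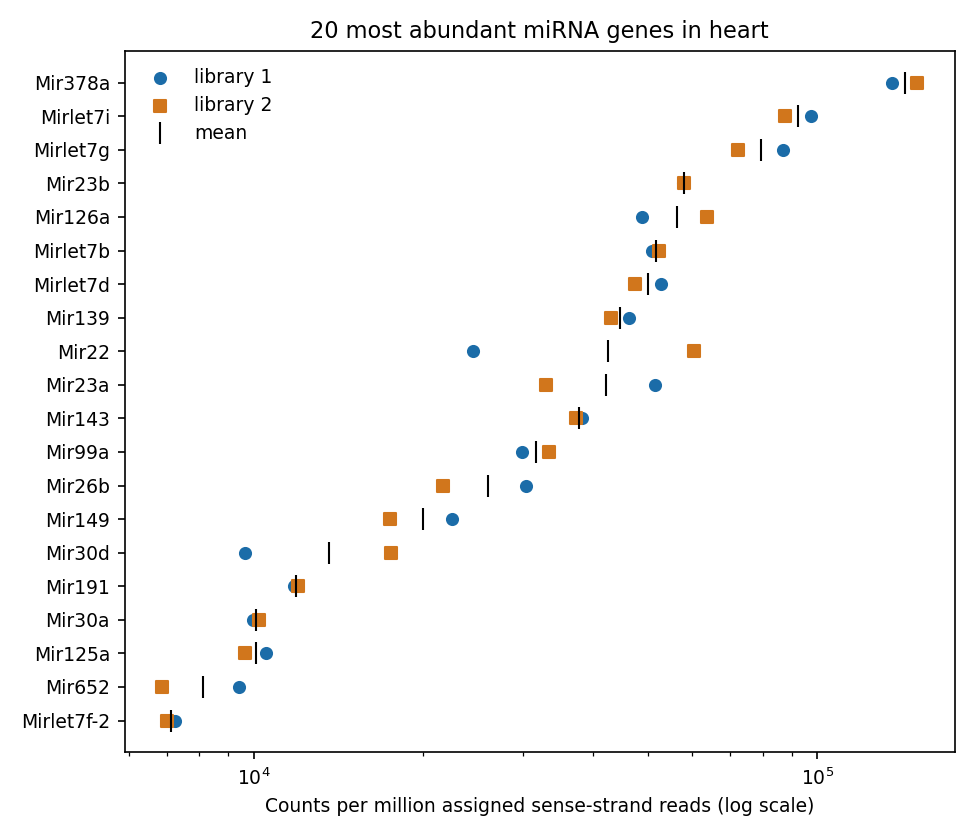
Levels of the 20 most abundant miRNA genes in CPM of assigned sense-strand reads, on a log axis, with circles for library 1, squares for library 2 and a bar for the mean. Mir378a has the highest mean at 143048 CPM, and Mir22 has the widest gap between the libraries, from 24473 CPM in library 1 to 60488 CPM in library 2.

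Detection was limited to a small part of the annotation. Of 2202 annotated miRNA genes, 652 had a count in at least 1 library and 1550 had none, which allows up to 1.5 CPM in library 1 and 1.61 CPM in library 2 (3 counts) where a locus has no near-identical copy. Of the 1550, 932 share a 22 nt stretch with another miRNA locus, and a count of 0 sets no limit for them. At 10 CPM or more, 266 genes were detected in library 1, 253 in library 2 and 243 in both. At 1000 CPM or more in both libraries there were 63 genes, and 141 genes had a mean of 100 CPM or more. These limits and the intervals below cover counting error only. The labels say nothing of molecular identifiers, and without them PCR reads are not independent molecules.

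Among the cardiac muscle miRNAs, those carried inside myosin heavy chain genes made up nearly all counted reads. Mir208a, in an intron of the alpha myosin heavy chain gene Myh6 (chromosome 14, 54949060 to 54949142, minus strand), stood at 5198 ± 2553 CPM. Mir499, in an intron of Myh7b (chromosome 2, 155622880 to 155622958), stood at 2239 ± 1277 CPM, and Mir208b, in an intron of the beta myosin heavy chain gene Myh7 (chromosome 14, 54975700 to 54975776), at 126.8 ± 33.6 CPM. Mir1a-2 was at 56.1 ± 1.95 CPM, while Mir1a-1 (2.32 ± 0.250), Mir133a-1 (2.06 ± 0.629) and Mir133a-2 (2.04 ± 1.36) were within a few reads of 0. Each of these 4 loci shares a stretch of 22 nt with another miRNA locus, so their counts are uncertain. The 7 genes together took 0.763% ± 0.131 of assigned reads, 0.856% in library 1 (exact 95% interval 0.843 to 0.868) and 0.670% in library 2 (0.658 to 0.681). Their median level lay at percentile 91.75 of 10000 random gene lists of the same size, a description of these libraries and not a test.

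Mir208a exceeded Mir208b in both libraries. The host transcripts were not measured here. The ratio was 46.5 in library 1 (exact 95% interval 41.5 to 52.3) and 32.9 in library 2 (28.5 to 38.2), a mean log2 ratio of 5.29 ± 0.353. Both intervals exclude a ratio of 1. An exact sign-flip test over 2 libraries cannot give a two-sided p under 0.5.

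Markers of the other cells of the heart were present at different levels. The endothelial list took 5.64% ± 1.05 of assigned reads, nearly all on Mir126a. The smooth muscle list took 3.91% ± 0.0579, with Mir143 at 37774 ± 705 and Mir145a at 1333 ± 125 CPM. The leukocyte list took 0.683% ± 0.00812, led by Mir155 (3341 ± 492 CPM), Mir342 (1681 ± 206) and Mir150 (1289 ± 284), with Mir142 at 307 ± 61.1 and Mir223 at 217 ± 17.7. The erythroid list took 0.221% ± 0.0341, from Mir486 (1177 ± 22.7 CPM), Mir451a (892 ± 316) and Mir144 (141 ± 2.44), miRNAs known from red blood cells. The fibroblast and mesenchymal list took 0.184% ± 0.0907, from Mir214 at 1831 ± 906 CPM, which overlaps an annotated exon of Dnm3os, while its Mir199 members share sequence among loci.

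Lists of other tissues had low counted shares. The epithelial list took 0.0715% ± 0.0336, with Mir200c at 452 ± 202 and Mir203 at 119 ± 34.5 CPM. The neuronal list took 0.0229% ± 0.00621, with Mir128-1 at 150 ± 34.6 CPM, but 12 of its 13 members share a 22 nt stretch with another locus, so its share can be undercounted. The hepatic and intestinal list took 0.0177% ± 0.00552, with the liver miRNA Mir122 at 66.0 ± 74.3 CPM. The pluripotent stem cell list took 0.0133% ± 0.0164, with Mir302b at 44.9 ± 55.0 CPM, and the skeletal muscle cluster 0.00520% ± 0.00659, with Mir206 at 50.9 ± 65.2 CPM. The pancreatic list was at 0.000288% ± 0.000124, with Mir217 at 2.36 ± 1.22 CPM. For the pluripotent stem cell list, the skeletal muscle cluster and Mir122 the SD exceeded the mean, because nearly all reads came from a single library.

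Among the families and genomic clusters, let-7 was the largest, with 29.3% ± 1.97 of assigned reads from 12 members, each at 100 CPM or more. The metabolic and stress list followed at 19.3% ± 3.96, from Mir378a, Mir22, Mir21a (3959 ± 3088 CPM), Mir34a (3247 ± 798) and the hypoxia-responsive Mir210 (184 ± 35.6). The mir-23/27/24 clusters took 10.7% ± 1.05, of which Mir27b gave 5249 ± 1685, Mir27a 1668 ± 690, Mir24-2 212 ± 30.0 and Mir24-1 105 ± 41.1 CPM, the last pair sharing sequence. The mir-30 family took 3.19% ± 0.341, with Mir30e at 6629 ± 2388 CPM. The mir-26 family took 2.62% ± 0.596, with most counted reads on Mir26b. The 2 Mir26a loci among its 3 members share a 22 nt stretch, so Mir26a can be undercounted and the make-up of the family is uncertain. The mir-17-92 and paralog clusters took 1.26% ± 0.327, led by Mir93 at 5754 ± 2061 and Mir17 at 2065 ± 328.6 CPM. The mir-15/16 family took 1.21% ± 0.0597, led by Mir322 at 5356 ± 819 and Mir15b at 2441 ± 222 CPM, and the mir-29 family 0.475% ± 0.0136, of which Mir29a gave 4470 ± 3.18 CPM. A 22 nt stretch is shared with another locus by 6 of 12 let-7, 2 of 7 mir-30 and 4 of 15 mir-17-92 and paralog members. The same holds for 2 of 9 mir-15/16 and 3 of 4 mir-29 members. Such members can be undercounted, so these shares and leading members describe counted reads only. The imprinted Dlk1-Dio3 cluster took 0.437% ± 0.138, led by Mir127 (1519 ± 768 CPM), Mir411 (586 ± 121) and Mir541 (518 ± 71.4). The Sfmbt2 cluster took 0.124% ± 0.0187, with Mir467d at 814 ± 126 CPM, and 79 of its 81 members share sequence with another locus. Entries resembling ribosomal RNA took 0.00811% ± 0.00319, with Mir6236 at 67.2 ± 26.4 CPM.

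**Figure D2:**
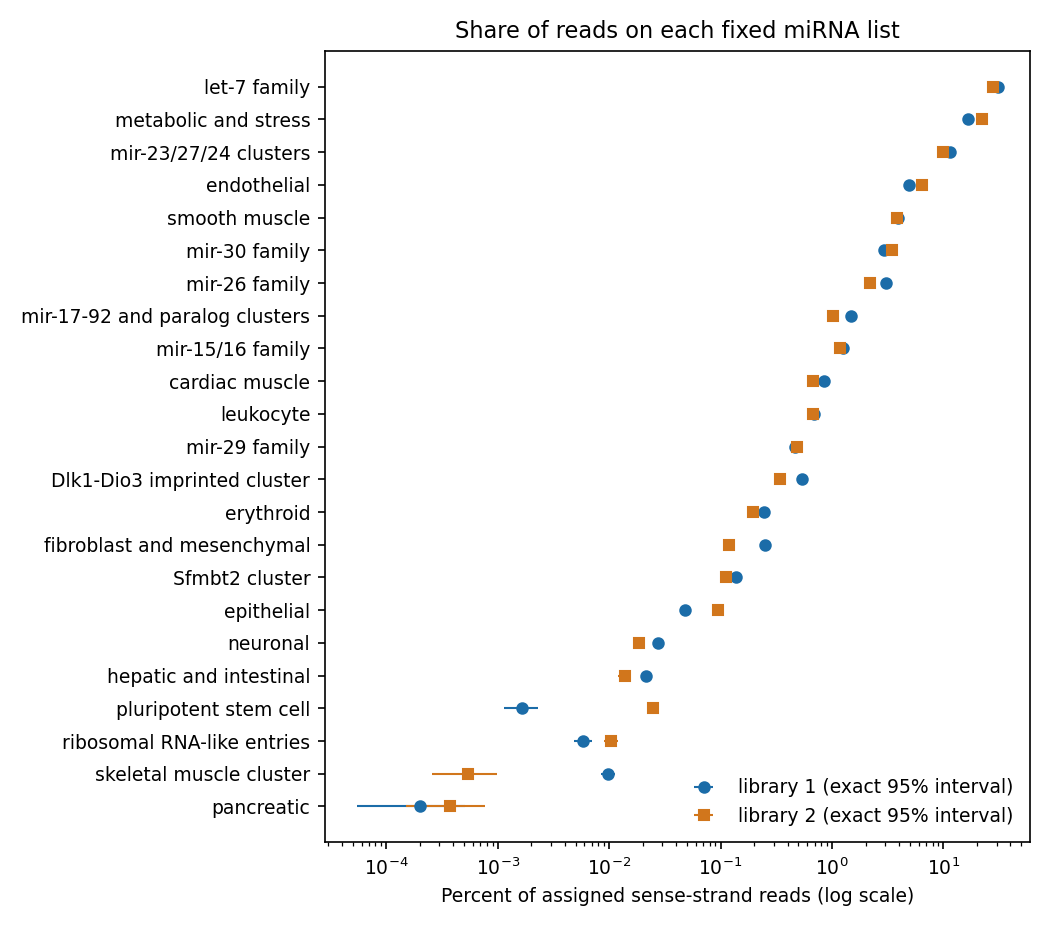
Percent of assigned sense-strand reads on each of the 23 miRNA lists, on a log axis, with circles for library 1, squares for library 2 and exact 95% intervals as bars, many smaller than the symbols. The let-7 family has the highest mean share at 29.3%, the cardiac muscle list has 0.763%, and the pluripotent stem cell and skeletal muscle lists stand farthest apart between the libraries. Lists with members that share a 22 nt stretch with another locus, such as 4 of the 7 cardiac muscle genes, can be undercounted.

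The libraries were next compared with each other. Levels were similar in rank, and a set of well-covered genes nevertheless differed severalfold. Across the 344 genes with 10 or more counts summed, Spearman's rho was 0.942 (bootstrap 95% interval over genes 0.918 to 0.961) and Pearson's r of log2(CPM + 1) was 0.964, where genes are not independent replicates. The biological coefficient of variation, the relative spread of a gene between libraries beyond counting, was 0.421 (bootstrap 95% interval 0.352 to 0.486). Of the 141 genes at a mean of 100 CPM or more, 101 lay within 1.5-fold and 17 differed by 2-fold or more with an adjusted p under 0.05, 10 higher in library 2 and 7 higher in library 1. With scaling by the trimmed mean of M-values (TMM), the split of these well-covered genes was 14 higher in library 2 and 2 higher in library 1.

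Higher in library 2, as log2 ratios of library 2 over library 1 after scaling to assigned totals, were Mir26a-2 (3.73, within Ctdsp2), Mir21a (1.79, within Vmp1), Mir140 (1.69, within Wwp2), Mir674 (1.69) and Mir31 (1.5). The hairpins within these 3 host genes overlap an exon of at least 1 annotated transcript and can be intronic in others. Mir26a-2 rested on 54 and 675 reads and shares a 22 nt stretch with Mir26a-1. Mir22 (1.31) and Mir499 (1.23) also passed both criteria. Higher in library 1 were Mir185 (-3.24, in an intron of Tango2), Mir222 (-1.49), Mir487b (-1.16), Mir130b (-1.14) and Mir127 (-1.08), and also Mir214 (-1.05) and Mir208a (-1.05). TMM scaling added 0.19 to every log2 ratio, the size of the median log2 ratio of tested genes (-0.19). With it Mir487b (-0.97), Mir130b (-0.95), Mir127 (-0.89), Mir214 (-0.86) and Mir208a (-0.86) no longer reached 2-fold, while Mir200c (1.14), Mir27a (1.06), Mir30d (1.05) and Mir24-1 (1.01) did so in library 2, as did Mir6236 (1.01), which is under 100 CPM.

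**Figure D3:**
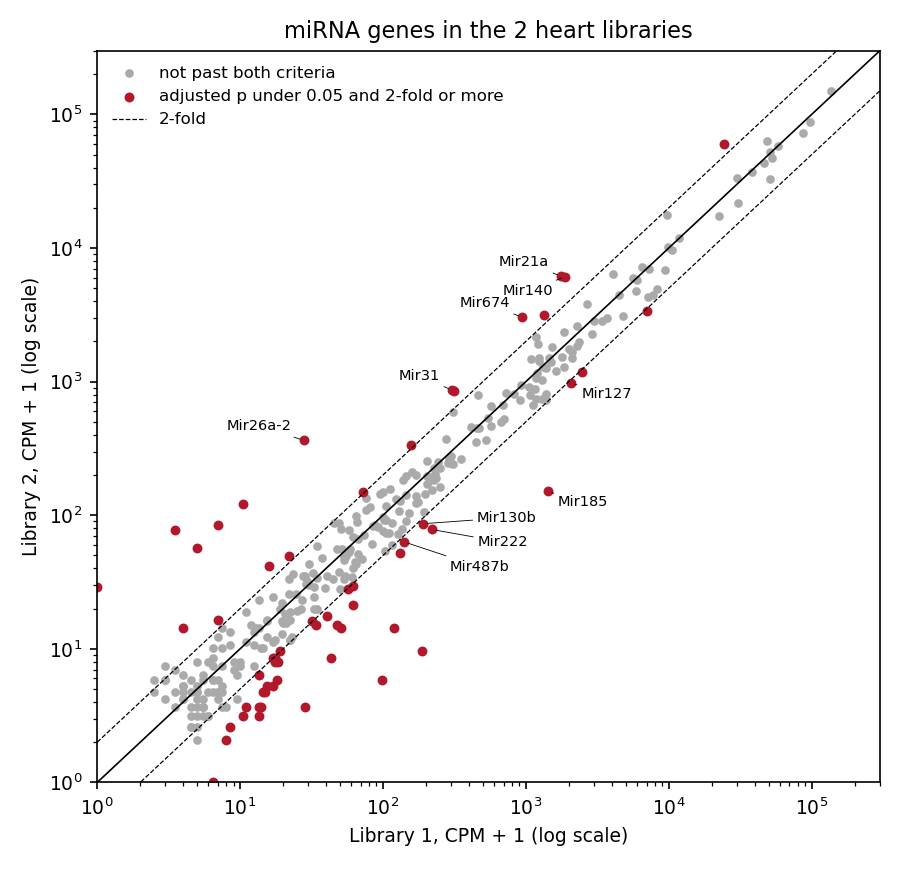
CPM + 1 of the 344 tested miRNA genes in library 1 (horizontal, log axis) and library 2 (vertical, log axis), with the line of equality and dashed 2-fold lines. Red points are the 59 genes with an adjusted p under 0.05 and a 2-fold or larger ratio, and the 5 largest ratios in each direction at a mean of 100 CPM or more are named.

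Over all 344 tested genes, 59 differed by 2-fold or more with a Benjamini-Hochberg adjusted p under 0.05 in the exact conditional binomial test, 19 higher in library 2 and 40 higher in library 1. With TMM or DESeq2 scaling the split was 28 higher in library 2 and 27 higher in library 1, so the excess in library 1 depended on the scaling. Without the fold criterion, 186 genes passed the adjusted p. This test sets 2 libraries against each other on read counts, models counting error and no spread between samples, and says nothing about conditions.

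By list, 11 of 42 tested members of the Dlk1-Dio3 cluster were higher in library 1 and 0 higher in library 2 by both criteria, and 7 against 0 with TMM scaling. By adjusted p alone, 23 of its members passed over all genes tested and 23 adjusted over the list alone, and the 2 adjustments gave equal counts for each of the other lists too. The pluripotent stem cell list had 463 reads in library 2 against 33 in library 1 (list log2 ratio 3.89), and all 4 tested members were higher in library 2. The epithelial list was also higher in library 2 (0.996), with 3 of 8 tested members higher there, and 4 with TMM scaling, among them Mir200b, named after its values were seen, at 226 against 19 reads, and 1 higher in library 1. The skeletal muscle cluster was higher in library 1 (-4.13), with Mir206 at 194 reads against 9, and so was the hepatic and intestinal list (-0.65), with Mir122 at 237 against 25 reads and its median member at 0.07. The fibroblast and mesenchymal list (-1.05) was higher in library 1 with both scalings, but none of its members passed both criteria with TMM scaling. For the smooth muscle, leukocyte, let-7 and mir-15/16 lists the direction turned between scalings, and no member of these lists passed both criteria with either scaling.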

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

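In this part, the tests of shared loci, of cluster and family pairs, of the share of heart cells and of stem cell RNA were chosen or changed after results had been seen (for pairs, the quartiles and the checks on fewer pairs came after the result permuted over all genes), while those of the antisense neighbour and of GC content were written before.

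Reads that mapped to several places stood out as signal outside the measured genes, at 2273922 in library 1 and 2098983 in library 2, or 42.2% ± 0.987 (SD, n = 2) of all reads against 37.3% assigned. A second such signal was the antisense column of single genes with no miRNA gene opposite, set against the 3 counts that a count of 0 allows for a gene. Mir122 exceeded it with 28 antisense reads in library 1 and 32 in library 2, while Mir203 (24 and 2) and Mir5620 (4 and 0) did so in library 1. With 2 libraries and 1 group, neither outlying samples nor differences between groups was tested.

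The first pattern weighed is the near absence of counted reads for Mir1a and Mir133a, abundant miRNAs of heart muscle, whose 4 loci held 242 reads in both libraries together. The only annotated miRNA gene opposite any of these loci is Mir1b, opposite Mir1a-2. Mir1b held 6 reads, which argues against counting on the antisense neighbour for Mir1a-2. The other loci have no such neighbour, so the 6 reads say nothing of them. A candidate explanation is that reads from loci sharing their mature sequence were left uncounted as mapping to several places. All 4 loci share 22 nt with another locus, and in 16 of 20 other genomic clusters the sharing members were lower than their neighbours (median log2 difference -4.63, exact one-sided sign test p = 0.00591). Several of these clusters hold copies of the same miRNA, such as Mir24-1 and Mir24-2, so they are not independent and the p of the sign test can be too small. This evidence is indirect, since it comes from other clusters and the reads mapping to several places were not traced to a locus, and no biological explanation was tested.

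The second pattern is the set of differences over 2-fold between the libraries. GC content of the hairpin is argued against as the whole cause, with a Spearman correlation of -0.133 (permutation p = 0.0508) over 216 genes with 100 or more counts. The GC content of the mature miRNA was not measured, so a step that depends on it stays open. A step that depends on RNA sequence, such as adapter ligation, would move miRNAs of the same family at different loci together, and 109 such pairs were closer than pairs permuted within abundance quartiles (one-sided permutation p = 0.00796, and 0.000530 permuted over all genes), but not detectably so without let-7 (48 pairs, p = 0.284) or over the 6 pairs that held a gene past both criteria (p = 0.509). Transcription of whole clusters that differed between the samples may also contribute. The 111 pairs of cluster neighbours with different name numbers were closer than permuted pairs (one-sided permutation p = 0.00143, 0.000940 over all genes, 0.00787 without chromosome 12). Over the 23 pairs that held a gene past both criteria, p was 0.0001, the smallest these permutations can give, yet 21 of those 23 pairs lay on chromosome 12. Some of these neighbours are relatives, such as Mir15a and Mir16-1 of the mir-15/16 family. The pairs therefore do not keep sequence likeness apart from shared transcription. Both explanations, a sequence-dependent step and cluster transcription, therefore stay open for most of the differing genes. Litter was not tested, and cell composition was looked at only through the markers of the third pattern.

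The third pattern is that markers of other tissues differed between the libraries. A lower share of heart cells in 1 library would raise all of these lists there only if the other cells came from all of these tissues. The lists moved apart, which argues against such a mixture as the whole cause, though the lower side rests on Mir206 alone (194 reads in library 1, 9 in library 2). The lists cannot decide on a lower share of heart cells in general, since each library could hold cells of a different other tissue. The tested cardiac muscle genes, looked at after results had been seen, also moved apart. Mir208a (-1.05) and Mir208b (-0.55) were higher in library 1 and Mir499 (1.23) in library 2, with Mir1a-2 at -0.07. A changed share of cardiac muscle cells alone would move them the same way. For these genes, the values argue against it as the whole cause. Of 5 lists, 2 (pluripotent stem cell, log2 ratio of tested members 4.26, and epithelial, 0.996) lay above the 95% range of 10000 random lists matched on mean CPM. The skeletal muscle list (-4.25 against a range of -3.12 to 3.75) lay below it on its 1 tested gene, Mir206. For a list of 1 gene, the range comes from single genes of similar level, Mir206 among them. Its ends are the ratios of Mir122 and Mir302b, so the range adds nothing to the ratio of Mir206 itself. The neuronal (-0.56) and the hepatic and intestinal (-0.65) lists lay inside their ranges. Mouse embryonic stem cell RNA in library 2 is argued against, because the Mir290 to Mir295 genes held 7 reads there against 455 on the Mir302 genes, or 1.54% (upper 95% bound 3.20%). Carry-over from libraries of other samples, tissue left on the heart at dissection and differences between the mice were not tested and remain open.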

How the results depend on the processing

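All alternatives were chosen before the data were examined. Of 37 recomputed main values, 9 moved. A count moved if it changed by more than 1.5-fold, and a share if it changed by its SD or more. A correlation or coefficient of variation moved if it left its interval, and the ratio of Mir208a to Mir208b if it changed sign. By this rule leaving out a replicate cannot move a share, and the split of differing genes by direction did not enter. With a threshold of 1 CPM 393 genes were detected in both libraries, and 130 with 100 CPM. With both strands counted together the share of the 10 most abundant genes was 68.8% and that of the cardiac muscle list 0.980%, since genes with a miRNA gene opposite lose their counts. As percent of all reads, the same shares were 24.6% and 0.284% by the larger denominator. Without a count filter Spearman's rho was 0.882. Without a fold criterion 186 genes differed between the libraries, and 105 with 1.5-fold. Leaving out a replicate gave 253 to 266 genes detected, 65.3% to 66.8% for the top 10, 0.670% to 0.856% for the cardiac muscle list and a log2 ratio of Mir208a to Mir208b of 5.04 to 5.54. Another pseudocount cannot move a rank correlation. The coefficient of variation stayed between 0.419 and 0.427.

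TMM and DESeq2 scaling gave 55 differing genes in place of 59, but 28 higher in library 2 and 27 in library 1 in place of 19 and 40, and 4 lists turned direction. With them, 44 values of named genes were recomputed, each gene once with TMM and once with DESeq2 scaling. These genes were picked partly by result, since each passed both criteria with at least 1 scaling. Named genes without a call in any setting were left out, as was Mir29c, which passed with assigned totals. The tally is therefore not a rate over all named genes. Of the 44 values, 24 kept direction and call. Because of the added 0.19, 10 lost the call (Mir208a, Mir214, Mir127, Mir130b and Mir487b) and 10 gained one (Mir30d, Mir27a, Mir24-1, Mir200c and Mir6236). No paired analysis was possible because the labels give only 1 group. Depth limits the lowest genes, where 3 counts are 1.5 and 1.61 CPM.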

Other observations

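Neighbouring miRNAs of a cluster did not always stand together, in values chosen after they were seen. Mir143 was at 37774 ± 705 CPM (SD, n = 2) and Mir145a, its neighbour on chromosome 18, at 1333 ± 125. On chromosome 8, Mir23a was higher in library 1 (log2 ratio of library 2 over library 1 -0.64) and its neighbour Mir27a higher in library 2 (0.87). On chromosome 14, Mir15a stood at -0.92 and Mir16-1 at 0.78, though Mir16-1 shares sequence with Mir16-2. On the X chromosome, Mir222 stood at -1.49 and Mir221 at -0.18. TMM scaling adds 0.19 to each of these ratios and leaves their signs as they are, except for Mir221, which comes to just above 0.

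Mir146, the annotation's name for a gene outside the leukocyte list as it was written, stood at 2089 ± 361 CPM (SD, n = 2). The Mir302 genes held 25 reads in library 1 and 455 in library 2, while the Mir290 to Mir295 genes held 8 and 7. Mir1839 (log2 ratio 1.42), Mir29c (1.10) and Snord43 (1.05), an entry named for a small nucleolar RNA, were the other genes at 100 CPM or more that were higher in library 2 by both criteria.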
